A study of Rattus norvegicus with 16 samples.

How the data were processed

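Total RNA from 3 regions of the newborn rat cochlea was measured on 16 Affymetrix Rat Neurobiology U34 arrays, each from a pool of 12 cochleae. The deposited table holds an intensity for each of 1322 probe sets on a linear scale. The authors had scaled each array to one target, since the 2% trimmed mean was 2500 on every array, and the software of the summary was not stated. The other deposited files were records of the fluidics and scanner runs, which hold no expression values and were used for the chip type and the scan session. The native arrays were scanned in session 1, the first repeats of the cultures in session 2 and the second repeats in session 3.

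Values were used as deposited, as log2(value + 16). The 59 control probe sets were left out of the tests and used for RNA integrity (ratio of 3′ to 5′ probe sets) and background, which left 1263 probe sets. A group with no array above the 95th percentile of its own 23 foreign-sequence controls counted as not above background. At-least folds have the signals of such groups raised to that percentile, and none is given where groups on both sides were affected, a choice made after the results were seen. Of these 1137 carried 1 gene symbol, 8 several and 118 none, and symbols were matched to a current gene table by gene number for 1132. The 720 genes were represented in list tests by the probe set with the highest mean, and 276 had more than 1.

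Arrays were grouped by region and condition into 9 groups. A linear model with 1 mean per group was fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with 7 residual degrees of freedom and empirical Bayes moderation with a variance trend, so that the single arrays of native modiolus and native stria vascularis were assumed to vary like the other groups. Contrasts were hypoxia minus normoxia and normoxia minus native, each in every region and as the mean of the 3 regions, the 3 differences between regions as the mean of 3 conditions, and moderated F tests of whether a difference varied between regions. Tests were two-sided, with Benjamini-Hochberg adjustment over the 1263 probe sets of a contrast and a threshold of 0.05. Errors are standard errors of the model. Groups, contrasts, gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

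Genes were named by rule, each by its brightest probe set: for the averaged and region contrasts, the 10 largest changes each way among passing probe sets with 1 symbol, a level above the median in the higher group and the same sign in all 3 regions or conditions; within 1 region, the 5 largest each way; where fewer than 5 passed, the 5 smallest p values each way, given as not passing, beside any probe set that passed; and a few hypoxia and stress genes in every case, of which Vegfa was not on the array and one other is not reported here, whatever its value. Up to 4 members were taken from each list.

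Of 26 lists of cell types and processes, those with at least 4 measured genes were tested with camera, which compares a list with all other genes, with a preset correlation of 0.01 between genes and again with an estimated one. The test named fry asks whether the genes of a list move on balance one way, without comparing them with other genes. The estimated correlation kept 2 of 8 calls for culture, 0 of 2 for hypoxia, 2 of 6 for the organ of Corti against the stria vascularis, and 0 of 2 and 0 of 5 in the other region comparisons. The model was tested on simulated data with 200 of 1263 probe sets changed: for hypoxia averaged over the regions it recovered 61.4% of 2-fold and 93.2% of 4-fold changes, for 1 region 26.2% to 28.8% and 64.8% to 67.8%, and for a hypoxia effect that differs between regions 7.4% and 35.8%. These shares hold for that many changes, from 1.5-fold to 8-fold, and for noise without a session effect. Recovery where only few probe sets change was not simulated and can be lower. In 10 simulations camera called the shifted list each time and 0 of 180 unshifted lists. The simulated genes varied independently of one another, so that these simulations cannot test the preset correlation.

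Alternatives were other pseudocounts, quantile normalization, centring of each array on its median, a filter on dim probe sets, no variance trend, array weights, the replicate block, scan session as a term or random block, a model of only the arrays compared, single conditions, and leaving out each array in turn. The replicates were not treated as paired in the main model. Residuals of arrays with the same repeat number correlated at r = -0.01 to 0.28 over 15 pairs of groups. Of these, 10 lay above the threshold of 0.1, so that the main model leaves out an effect shared by repeats. As the repeat is also the scan session, values with the session as a term are given beside part of those for hypoxia.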

Results

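Messenger RNA was measured on 16 arrays from the inner ear of newborn rats, each array holding total RNA pooled from 12 cochleae. Tissue came from 3 regions of the cochlea: the organ of Corti, which carries the sensory hair cells, the modiolus, which carries the spiral ganglion and its nerve fibres, and the stria vascularis, the secretory epithelium that makes endolymph. Each region was studied in 3 conditions: native tissue taken straight after dissection, explants kept for 24 h in normoxic culture, and explants cultured for the same time that passed through 5 h of hypoxia. Hypoxia began 3 h after plating at an oxygen pressure of 10 to 20 mmHg, and the explants then recovered in normoxia for 16 h. Each of the 6 cultured groups and the native organ of Corti had 2 arrays, while native modiolus and native stria vascularis had 1 array each. The array covers 720 named genes chosen for their interest to neurobiology, so that broad classes such as the cell cycle are not represented. The median signal per array ranged from 555.4 to 939, and the 95th percentile of the 23 control probe sets against sequences foreign to the rat ranged from 237 to 772. A group with no array above this percentile of its own controls is called not above background. Differences against such a group are also given as at least a fold, with its signals raised to that percentile, and the fitted log2 values of these genes depend on the background. The small number of arrays limits the precision of every value given here. Within groups, arrays correlated across probe sets at r = 0.918 to 0.955, normoxic with hypoxic arrays of the same region at 0.914 to 0.956, cultures of different regions at 0.827 to 0.911, and native with cultured arrays of the same region at 0.775 to 0.871.

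Explants kept for 24 h in normoxic culture were compared with native tissue, which served as their control, to see what dissection and culture did to each region. The mean signal over arrays of Ccl2, which attracts monocytes, was 612 in native tissue and 38600 in culture. Its fitted rise, from the mean of the within-region log2 differences, was 52.7-fold (log2 difference 5.72 ± 0.19 (SE), adjusted p = 2e-10). Ccl3 rose by 5.82 ± 0.23 on the log2 scale, Cxcl2 by 5.20 ± 0.33 and Ccl20 by 4.02 ± 0.19. Mt2A, a metal-binding metallothionein, rose 51.1-fold (5.67 ± 0.11, adjusted p = 1.7e-12), the heme-degrading enzyme Hmox1 11.2-fold (3.49 ± 0.12, adjusted p = 2.2e-10) and the complement component C3 by 5.01 ± 0.16. A second probe set of C3 and of Hmox1 rose at least 20.2-fold and 53-fold, for Hmox1 more than the first. The transcription factors Cebpb (3.79 ± 0.13) and Fosl1 (3.26 ± 0.36) and the cytokine Il1b (3.51 ± 0.28) also rose. In native tissue Ccl3, Cxcl2, C3 and Fosl1 were not above background in any region, and Ccl20 and Il1b were not in 2 regions, so that these rises were at least 9.76-fold, 4.76-fold, 18.6-fold, 2.5-fold, 12.5-fold and 5.5-fold. Other transcripts fell. Fez1, an adaptor of axonal transport, fell by 4.02 on the log2 scale (SE 0.37, adjusted p = 4e-06), the glial calcium-binding protein S100b fell by 2.48 (SE 0.11, 5.56-fold, adjusted p = 4.5e-09) and the neurofilament Nefm fell by 2.06 (SE 0.34). The synaptic ligand Nxph1 (-2.71 ± 0.49), the sodium leak channel Nalcn (-2.64 ± 0.54), the G protein subunit Gnao1 (-2.58 ± 0.34), the potassium channels Kcnd2 (-2.44 ± 0.58) and Kcna1 (-2.13 ± 0.39), the neurturin receptor Gfra2 (-2.21 ± 0.37) and the caspase Casp2 (-2.21 ± 0.20) fell as well. For Casp2 another probe set passed in the opposite direction. In culture Nxph1 and Kcnd2 were not above background in any region, Fez1 and Kcna1 in 2 regions and Gnao1 and Nalcn in 1. Their falls were at least 1.79-fold for each of the first 2, then 4.48-fold, 3.09-fold, 4.64-fold and 3.62-fold. Nefm was not above background in native or normoxic stria vascularis, so that no bound is given. For each of the 25 named genes that passed, all 6 normoxic arrays differed in the same direction from the native mean of their region. Most of these genes were named for large differences of one sign in the same arrays, so that this is no independent check.

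**Figure D1:**
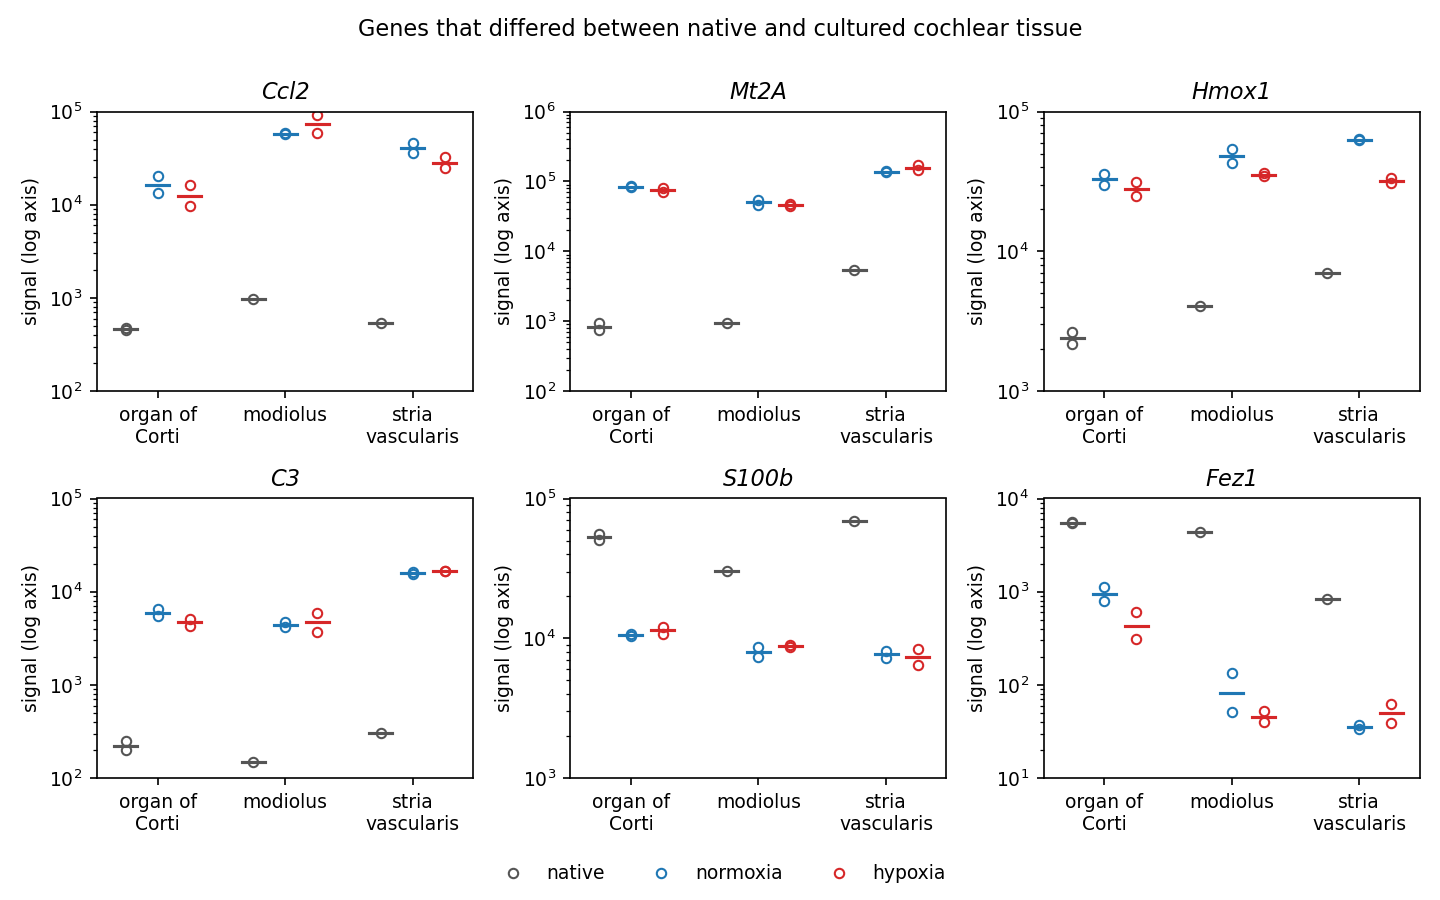
Signal of 6 genes on each array (circles, log axis) by region, with the geometric mean of each group as a bar; native modiolus and native stria vascularis have 1 array. Ccl2, Mt2A, Hmox1 and C3 were higher in every cultured array than in any native array, and S100b was lower; the mean of Fez1 in the organ of Corti was 5530 in native tissue and 958 in normoxic culture.

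The inflammatory and injury list had the smallest p of all lists. Of its 26 measured genes, 15 rose and 1 fell, and adjusted over the list alone 15 rose and 2 fell (camera adjusted p = 4.2e-08, and adjusted p = 0.0055 with an estimated correlation). Il1a and Il6 rose too, but were not above background in native tissue of any region nor in some of the cultures, so that no size is given. Genes of HIF targets and glycolysis rose in 6 of 7 cases, also when adjusted over the list alone (adjusted p = 1e-05, and 0.034 with an estimated correlation). Their differences were largest for Hmox1, then the transferrin receptor Tfrc at 2.45 ± 0.20 (at least 4.6-fold), the growth factor binding protein Igfbp3 at 2.28 ± 0.17, and the glucose transporter Slc2a1 at 1.86 ± 0.22. Hif1a itself rose by 1.57 ± 0.18, so that normoxic culture was already higher than native tissue in these genes. Of 8 antioxidant and detoxification enzymes, 5 rose and 1 fell, the same numbers when adjusted over the list alone (adjusted p = 6.4e-05, and adjusted p = 0.083 with an estimated correlation). Sod2, the mitochondrial superoxide dismutase, rose by 2.96 ± 0.43 and Gsta1 by 2.41 ± 0.15, while the neuronal metallothionein Mt3 fell by 1.05 (SE 0.31), with -3.08 ± 0.56 in the modiolus, -0.06 ± 0.46 in the organ of Corti and -0.02 ± 0.56 in the stria vascularis. Of 9 immediate early genes, 5 rose, also when adjusted over the list alone (adjusted p = 0.0028, and adjusted p = 0.2 with an estimated correlation). Jun rose by 2.59 ± 0.16 and Junb by 2.00 ± 0.17, whereas Fos was at 0.08 ± 0.14 (adjusted p = 0.72). Among 6 heat shock proteins and chaperones, 3 rose and 1 fell, and 4 rose and 2 fell adjusted over the list alone (adjusted p = 0.046, and adjusted p = 0.26 with an estimated correlation), and with quantile normalization the list lost its call (adjusted p = 0.14). Hspa1a rose by 1.94 ± 0.23 and Hspb1 by 1.43 ± 0.21, and Hspd1 of the mitochondrial matrix fell by 0.73 (SE 0.12). Hmox1 belongs to 3 of these lists. In the same arrays the ratio of the 3′ to the 5′ control probe set of GAPDH, a sign of RNA integrity, was 3.39 to 4.76 in native tissue and 1.07 to 1.39 in culture.

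The lists that fell were those of neurons, of Schwann cells and myelin, and of pumps and exchangers. Of 15 neuron genes, 8 fell and none rose, also when adjusted over the list alone (camera adjusted p = 0.025, and adjusted p = 0.32 with an estimated correlation), among them the neurofilaments Nefh (-1.94 ± 0.18) and Nefl (-1.85 ± 0.22) and the axonal tau protein Mapt (-1.46 ± 0.18). Nefl fell at least 3.23-fold, and the mean of Nefh rests in part on groups not above background. Of 7 genes of Schwann cells and myelin, 5 fell, and 6 fell adjusted over the list alone (adjusted p = 0.0036, and adjusted p = 0.083 with an estimated correlation). Besides S100b these included Mbp of the myelin sheath (-1.74 ± 0.25), the glial regulator Sox10 (-1.39 ± 0.22) and Cnp (-1.25 ± 0.14). Of 11 pumps and exchangers, 6 fell, also when adjusted over the list alone (adjusted p = 0.017, and adjusted p = 0.24 with an estimated correlation). The Na,K-ATPase beta subunits Atp1b1 (-1.68 ± 0.20) and Atp1b2 (-1.40 ± 0.22), the sodium-calcium exchanger Slc8a2 (-1.10 ± 0.15) and the calcium pump Atp2a3 (-1.05 ± 0.19) fell. Genes of cell death did not pass as a list (adjusted p = 0.14), although 8 of 18 fell and 1 rose, and adjusted over the list alone 8 fell and 2 rose. For culture 12 genes had probe sets that passed in opposite directions, among them Bax, Casp2, Bcl2l11 and Hrk here and Atp1b3 of the pumps. The counts of such lists depend on the probe set that stands for a gene. Bax was at -1.14 ± 0.12, while its 2 other probe sets passed in the opposite direction (1.12 ± 0.12 and 1.71 ± 0.17), and Bcl2 at -0.71 ± 0.31 (adjusted p = 0.097). The GAPDH ratio differed between the same arrays, at 3.39 to 4.76 in native tissue and 1.07 to 1.39 in culture.

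By limma, 404 of 1263 probe sets passed in the mean of the 3 regions, 168 higher and 236 lower in culture, and the median difference of all genes was -0.19, from which every change named for culture departed in its own direction. All native arrays were scanned in session 1 and no cultured array was, so that scan session and culture cannot be told apart. With session as a random block 355 probe sets passed, with the replicate block 432.

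In the organ of Corti 218 probe sets passed, 107 higher and 111 lower in culture. In the modiolus 264 passed, 128 higher and 136 lower, and in the stria vascularis 173, 93 higher and 80 lower. These counts are not comparable between regions, since native organ of Corti had 2 arrays and the other native regions 1 each. In the simulated data 25% of 2-fold culture changes were recovered in the organ of Corti, 15.6% in the modiolus and 15.8% in the stria vascularis. In the organ of Corti Mt2A rose by 6.62 ± 0.17 (98-fold), and Nxph1 (-3.13 ± 0.74), Kcna1 (-2.67 ± 0.59) and Fez1 (-2.53 ± 0.56) fell. In the modiolus Ccl3 rose by 6.63 ± 0.42 and the protease inhibitor Serpine2 by 4.78 ± 0.27, while Fez1 (-5.47 ± 0.68), Nefh (-5.11 ± 0.33) and the synuclein Sncg (-4.31 ± 0.57) fell. In the stria vascularis Ccl2 rose by 6.20 ± 0.35, Cxcl2 by 6.01 ± 0.61 and C3 by 5.62 ± 0.29, and S100b (-3.18 ± 0.21) and neuronatin, Nnat (-2.69 ± 0.53), fell. Against groups not above background, the falls of Nxph1 in the organ of Corti (at least 2.71-fold) and of Fez1, Nefh and Sncg in the modiolus (at least 7.33-fold, 25.8-fold and 12.2-fold) are bounds. So are the rises of Ccl3 in the modiolus (at least 18.1-fold) and of Cxcl2 and C3 in the stria vascularis (at least 5.6-fold and 31.6-fold). Without native organ of Corti replicate 1 the count in the organ of Corti was 121, without normoxic stria vascularis replicate 1 that in the stria vascularis was 109, and with only the arrays compared it was 85. The labels of the native modiolus and stria vascularis arrays name fresh tissue in one field and a 24 h culture in another. Their signals were 983 and 540 for Ccl2 and 4090 and 6960 for Hmox1, against at least 9640 and 24800 in every cultured array and at most 476 and 2670 in native organ of Corti.

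Whether culture changed a gene alike in the 3 regions was tested directly. Nefh fell by 5.11 in the modiolus (SE 0.33) and by 1.55 in the organ of Corti (SE 0.27), and was at 0.83 ± 0.33 in the stria vascularis (adjusted p of the difference = 0.00011). Sncg fell by 4.31 in the modiolus and rose by 3.13 ± 0.57 in the stria vascularis (at least 3.33-fold, adjusted p of the difference = 0.00092). Serpine2 differed in the same test (adjusted p = 0.00092), with 2.08 in the organ of Corti, 4.78 in the modiolus and 1.20 in the stria vascularis. The intermediate filament nestin, Nes (adjusted p = 0.00092), was at 1.30 in the modiolus and at -0.93 and -1.12 in the organ of Corti and stria vascularis, and the lysophospholipase Enpp2 (adjusted p = 0.0015) was at -0.09 in the modiolus and 0.93 and 2.43 in those regions. Of the 15 neuron genes, 9 fell and 1 rose in the modiolus, 6 fell in the organ of Corti, and in the stria vascularis 0 fell and 2 rose. In native stria vascularis Nefh, Nefm and Sncg had signals of 374, 455 and 175, not above background (485). A fall of these genes could hardly be seen there, and the regional differences of Nefh and Sncg rest in part on this floor. The test of a difference between regions passed for 5 of the 15 neuron genes, which were Nefh, Sncg, Gap43, Eno2 and Map2. By limma 42 probe sets passed this test, and the count was 81 with the replicate block, 68 with scan session as a random block, 88 with session 3 as a term and 14 without the variance trend. Without normoxic organ of Corti replicate 2 it was 26.

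**Figure D2:**
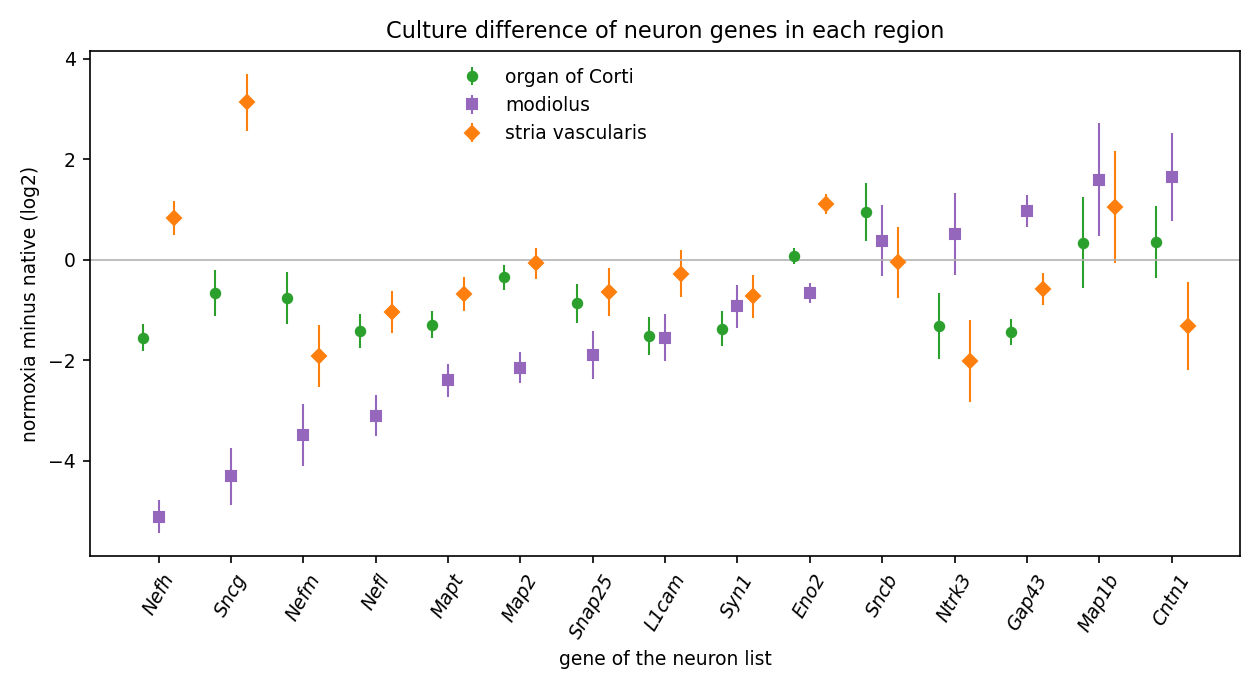
Culture difference (normoxia minus native, log2) of the 15 genes of the neuron list in each region, points with standard errors from the model; genes are ordered by the value in the modiolus. The modiolus lies at -5.11 for Nefh, -4.31 for Sncg and -3.10 for Nefl, with the organ of Corti at -1.55, -0.66 and -1.41. Nefh, Nefm and Sncg were not above background in native stria vascularis.

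Hypoxic and normoxic explants of the same age were compared to find what 5 h of hypoxia left behind after 16 h of recovery. Few genes passed. Nos2, the inducible nitric oxide synthase, passed on 1 of its 7 probe sets, with a mean signal of 551 in normoxic and 2390 in hypoxic explants (at least 3.52-fold, log2 difference 1.94 ± 0.30, adjusted p = 0.036, higher in 6 of 6 arrays). The other 6 Nos2 probe sets lay between -0.56 and 0.13, the smallest adjusted p being 0.54, so that the rise was seen by 1 probe set alone. In culture the same probe set had fallen by 2.95 (adjusted p = 2.8e-05, at least 7.12-fold), while the brightest Nos2 probe set had risen by 2.16 (adjusted p = 4e-06), so that the probe sets of this gene disagreed there too. Calcrl, a receptor of vascular peptides, passed on 1 of its 3 probe sets (1.95 ± 0.33, adjusted p = 0.044) at signals of 50.1 and 256, not above background in any cultured group, so that no fold is given, and its other probe sets were at -0.25 and 0.32. With scan session as a term, Hmox1 fell by 0.55 (SE 0.08, adjusted p = 0.02), from a mean signal of 47900 to 31800, and Ccl3 fell by 1.06 (SE 0.19, adjusted p = 0.042). Without that term the adjusted p of both was 0.056. The glutathione transferase Gsta1 (-0.64 ± 0.12) and the microglobulin B2m (-0.37 ± 0.07), which were singled out after their values were seen, passed with the session term as well (adjusted p = 0.046 for each). The other Gsta1 probe set, at -0.42, did not (adjusted p = 0.23). Each repeat had its own scan session. Hmox1 was at -0.56 in session 2 and -0.53 in session 3, Ccl3 at -1.08 and -1.03, Il1b at -0.84 and -0.87, Nos2 at 2.08 and 1.79, Calcrl at 1.58 and 2.32, Gsta1 at -0.45 and -0.83, and B2m at -0.33 and -0.40. Across all probe sets the differences of the 2 sessions correlated at r = 0.18.

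The glucose transporters Slc2a3 and Slc2a1 were at 0.65 ± 0.17 (adjusted p = 0.24) and 0.32 ± 0.19 (adjusted p = 0.84), and Hif1a at -0.16 ± 0.15, and none of these passed. The 7 measured HIF targets and glycolysis genes had a median of 0.24 (camera adjusted p = 0.89); none passed over all genes, and adjusted over the list alone 1 rose and 1 fell. Bcl2 (0.30 ± 0.27), Bax (-0.04 ± 0.10), Fos (0.15 ± 0.12), Jun (0.01 ± 0.14) and Hspa1a (0.05 ± 0.20) did not pass. Further genes with small p values that did not pass were the potassium channel Kcnh6 (1.13 ± 0.28, adjusted p = 0.2), the purine receptor P2ry4 (0.92 ± 0.24), the receptor Igf1r (0.62 ± 0.19), the transcription factor Isl2 (0.72 ± 0.22), Sncg (-0.97 ± 0.27) and Il1b (-0.85 ± 0.24, adjusted p = 0.3). The sizes of Kcnh6, P2ry4, Isl2 and Sncg rest in part on groups not above background. With scan session as a term none of these passed either, the adjusted p being 0.12 for Slc2a3, 0.11 for Kcnh6 and Il1b, and 0.16 for P2ry4.

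Inflammatory and injury genes lay lower as a list after hypoxia. The 26 genes had a median of -0.16 and a mean of -0.28 (camera adjusted p = 0.0027, 0.0032 with scan session as a term, and adjusted p = 0.076 with an estimated correlation). By limma 0 of them passed over all genes, and adjusted over the list alone 3 fell. Il1a was at -1.71 ± 0.57, the receptor antagonist Il1rn at -1.45 ± 0.35, Ccl3 at -1.06 ± 0.20 and the T cell chemokine Ccl5 at -0.92 ± 0.31, while Cd44 was at 0.78 ± 0.45. Of these, Il1a, Il1rn, Ccl5 and Cd44 were not above background in some groups of both kinds. For the 19 list genes above background in every cultured group the median was -0.09 and the mean -0.17, with 11 lower (adjusted p = 0.046), a test chosen after the values were seen. In both sessions alike 14 of the 26 genes were lower and 6 were higher. Nos2 stands in the list by its brightest probe set (-0.19 and -0.70), not the one that rose. Within the sessions the camera adjusted p of the list was 0.046 and 0.015. The 8 antioxidant and detoxification enzymes had a median of -0.09 (adjusted p = 0.014, 0.0036 with scan session as a term, and adjusted p = 0.55 with an estimated correlation). None passed over all genes, adjusted over the list alone 2 fell, and within the sessions the adjusted p was 0.26 and 0.015. With quantile normalization the antioxidant list had an adjusted p of 0.076.

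**Figure D3:**
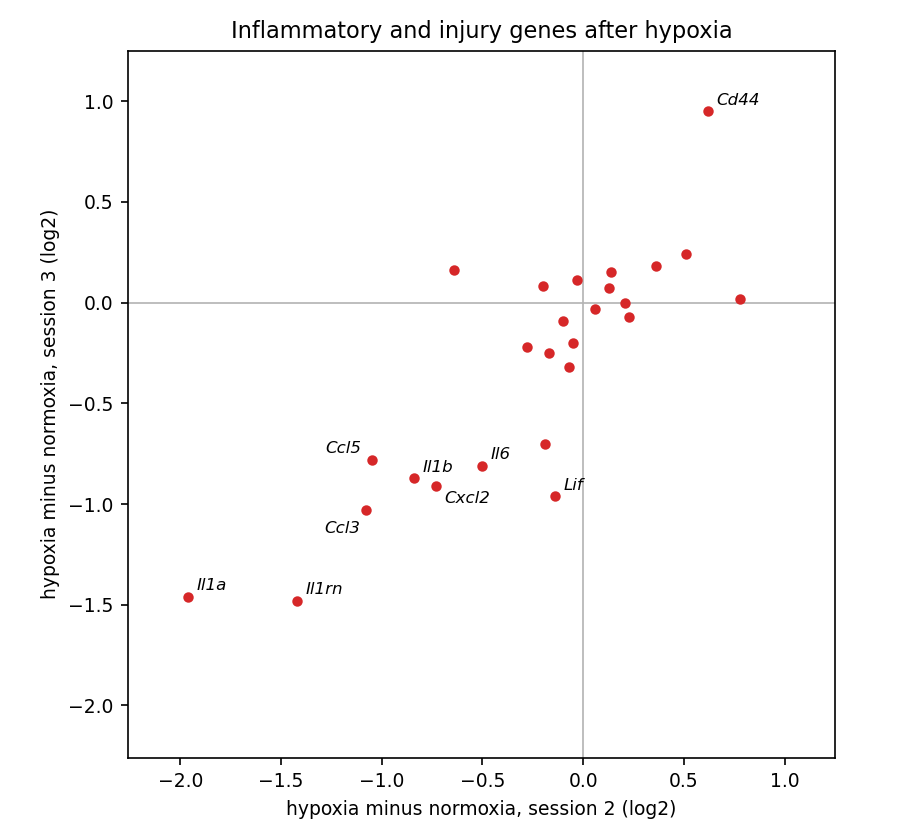
Log2 difference between hypoxic and normoxic explants (mean of 3 regions) of the 26 inflammatory and injury genes, repeat by repeat: session 2 on the horizontal and session 3 on the vertical axis, 3 hypoxic and 3 normoxic arrays in each. Il1a lies at -1.96 and -1.46, Il1rn at -1.42 and -1.48, and Ccl3 at -1.08 and -1.03; 14 genes are below 0 in both sessions.

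Of 1263 probe sets, limma passed 2 for the mean of the 3 regions, both higher, with 94 at an unadjusted p under 0.05 where 63.2 would come by chance. It passed 6 with scan session as a term, 4 with the replicate block and 5 with session as a random block, and each session alone gave 0. Leaving out single arrays gave 0 to 3, and the count was 0 in 11 of these cases.

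Within single regions few genes passed. In the stria vascularis the prion protein Prnp fell by 0.99 (SE 0.16, adjusted p = 0.034), Gsta1 fell by 1.32 on 1 of 2 probe sets (SE 0.21, adjusted p = 0.034, the other at -0.80 with adjusted p = 0.33) and Ccl5 fell by 3.08 (SE 0.54, adjusted p = 0.039), from a mean signal of 1200 to 115, which is not above background, so that the fall was at least 2.44-fold. Hmox1 (-0.96 ± 0.18, adjusted p = 0.055) and Slc2a3 (1.22 ± 0.30, adjusted p = 0.19) did not pass. With scan session as a term Hmox1 passed (adjusted p = 0.012, and 0.018 with session as a random block) and Slc2a3 did not (adjusted p = 0.11). In the modiolus the same Nos2 probe set rose by 3.31 ± 0.52 (at least 7.73-fold, adjusted p = 0.04), from 457 to 4710, while Gnao1 (2.28 ± 0.51) and the peptide Cck (1.75 ± 0.42) did not pass (at least 2.27-fold and 1.49-fold, adjusted p = 0.31 for both). In the organ of Corti limma passed 0 probe sets, with 57 at an unadjusted p under 0.05. The smallest adjusted p was 0.36, and the lowest p values among the probe sets kept by the rule for named genes were those of Ccl3 (-1.35 ± 0.34, adjusted p = 0.46), Fgf2 (-2.26 ± 0.61, at least 2.22-fold, adjusted p = 0.53) and P2ry4 (1.39 ± 0.42, adjusted p = 0.81). With the replicate block the modiolus gave 0 and the stria vascularis 5 probe sets, and with each array centred on its median both gave 0. Leaving out single arrays gave 0 to 2 in the modiolus and 0 to 5 in the stria vascularis, in most cases 0. A test of whether hypoxia acted differently between regions passed 0 probe sets by limma, with 66 at an unadjusted p under 0.05, so that no region was shown to differ from another. Prnp, Ccl5 and Adra1a came closest (adjusted p = 0.44).

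The 3 regions were then compared with one another, averaging native, normoxic and hypoxic samples with equal weight. Mean signals beside these differences are plain means over arrays. S100a1, a calcium-binding protein, had a mean signal of 27100 in the organ of Corti and 1530 in the modiolus (4.05 ± 0.11, 16.6-fold, adjusted p = 1e-10). The kappa opioid receptor Oprk1 (4.18 ± 0.40), Sncg (3.32 ± 0.29), the carboxypeptidase Cpz (2.96 ± 0.24), Atp1b1 (2.84 ± 0.19), the ephrin receptor Epha7 (2.80 ± 0.26) and Mt3 (2.51 ± 0.29) were higher in the organ of Corti too. So were Pak1 (2.65 ± 0.46) and the contactins Cntn1 (2.29 ± 0.45) and Cntn3 (2.59 ± 0.34), the last at a signal of 739 against 138. In the modiolus Cntn3 was not above background in any condition (at least 1.56-fold), nor were Pak1, Cntn1, Oprk1 and Sncg in 2 conditions (at least 1.93-fold, 3.39-fold, 14.2-fold and 6.59-fold) and Cpz, Epha7 and Mt3 in 1 (at least 7.32-fold, 5.99-fold and 5.52-fold). The modiolus had more Gap43, a protein of growing axons (-2.50 ± 0.16, 5.66-fold, adjusted p = 2.8e-07). It also had more Cnp of myelin-forming glia (-1.76 ± 0.13), Nes (-1.85 ± 0.11), the transcription factors Foxd1 (-2.60 ± 0.45) and Fosl1 (-1.87 ± 0.33), and the transporter Slc18a2 (-2.02 ± 0.47). Higher there, too, were the inflammatory signals Il6 (-3.43 ± 0.52), Ccl2 (-1.81 ± 0.18) and Il1b (-1.78 ± 0.26). In the organ of Corti Slc18a2, Foxd1 and Il1b were not above background in part of the conditions (at least 2.91-fold, 4.52-fold and 2.1-fold). For Il6 and Fosl1 both regions were affected and no bound is given. Of 26 inflammatory and injury genes 14 were lower in the organ of Corti, and adjusted over the list alone 16 were lower and 1 higher (camera adjusted p = 0.0018, and adjusted p = 0.066 with an estimated correlation). Of 15 neuron genes 8 were higher and 1 lower in the organ of Corti, and adjusted over the list alone 10 and 2 (adjusted p = 0.002, and adjusted p = 0.42 with an estimated correlation). Nefh was at 2.28 ± 0.17 (at least 4.39-fold) and Map2 at 1.36 ± 0.16, although another Map2 probe set passed in the opposite direction. The neuron difference was not seen in native samples alone, where 0 of 15 passed with a median of 0.32 (adjusted p = 0.38). Nefh was at 0.35 there and Map2 at -0.03, against 3.92 and 1.77 in normoxic cultures. The inflammatory list had an adjusted p of 0.044 in native samples and 0.0039 in normoxic cultures. By limma 302 probe sets passed, 144 higher and 158 lower in the organ of Corti, where the median of all genes was -0.19. With each array centred on its median 156 were higher and 110 lower. Native samples alone, with fewer arrays, gave 69, and 13 of the 20 genes named by size lost their call there. Of these, 7 lay under 0.5 of their averaged value in native tissue: Sncg at 1.01, Atp1b1 at 0.67, Pak1 at 0.71, Mt3 at 0.58, Gap43 at -0.84, Fosl1 at -0.51 and Nes at -0.52. The culture difference of Sncg, Atp1b1, Gap43 and Nes varied between the regions in the direct test (adjusted p = 0.00092, 0.0063, 0.016 and 0.00092), while that of Pak1, Mt3 and Fosl1 did not pass it. Mapk9 (-1.77 ± 0.57, adjusted p = 0.042) lost its call in 15 of the alternatives.

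**Figure D4:**
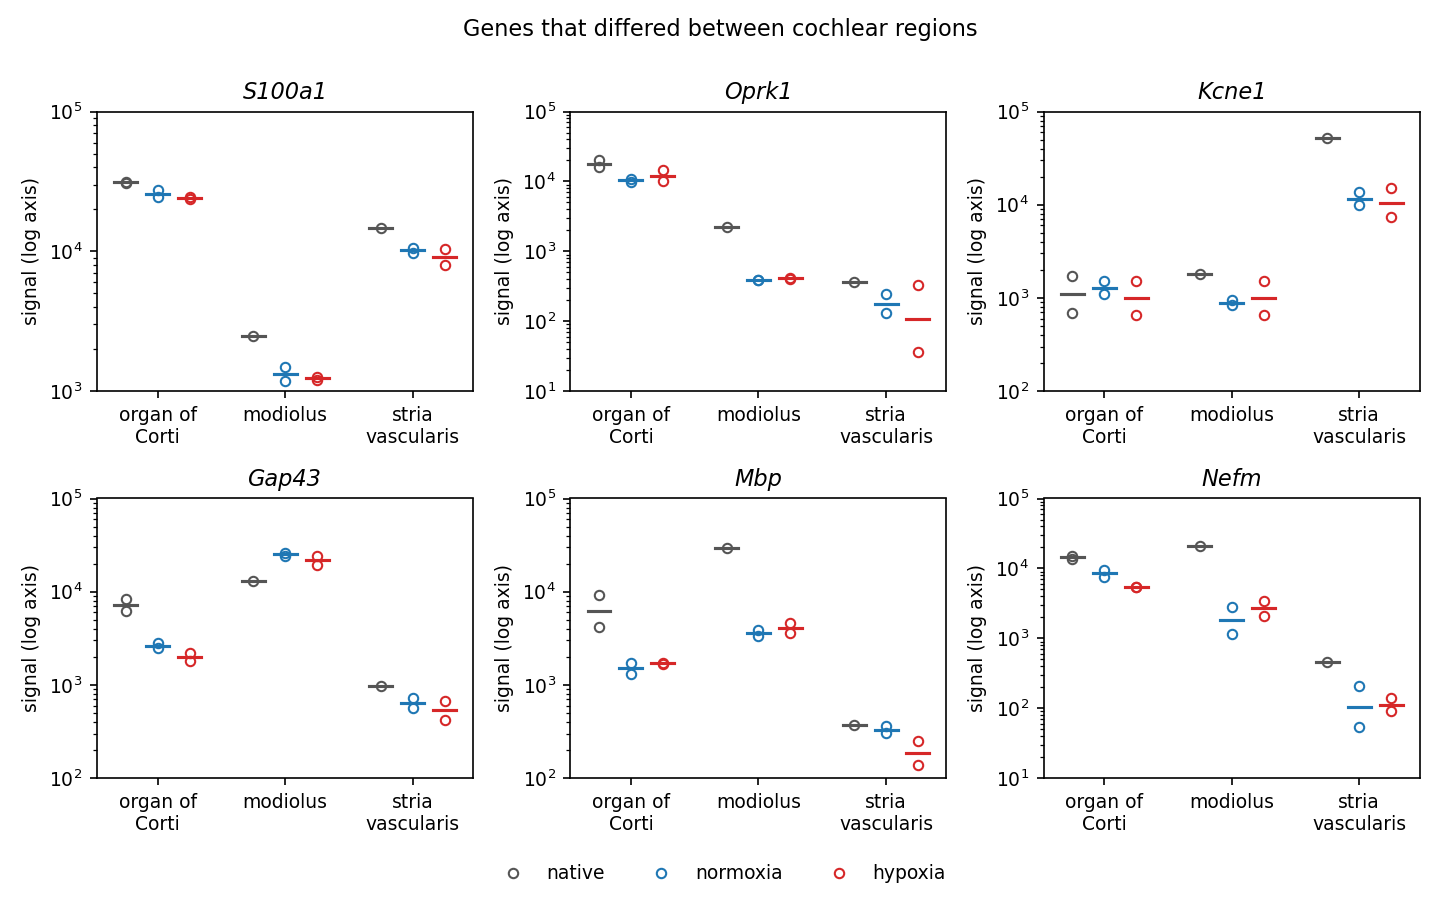
Signal of 6 genes on each array (circles, log axis) by region, with the geometric mean of each group as a bar. As plain means over the arrays of the 3 conditions, Kcne1 had a signal of 19600 in the stria vascularis and 1150 in the modiolus. S100a1 was at 27100 in the organ of Corti and 1530 in the modiolus, and Mbp at 9040 in the modiolus and 285 in the stria vascularis. The single native arrays were higher than the cultured ones, at 52100 for Kcne1 in the stria vascularis and 29700 for Mbp in the modiolus.

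The stria vascularis was set apart from the organ of Corti by the potassium channel subunit Kcne1 and by lower neuron genes. Kcne1, the beta subunit of the channel that secretes potassium into endolymph, had a mean signal of 1200 in the organ of Corti and 19600 in the stria vascularis (-4.03 ± 0.33, 16.3-fold, adjusted p = 3.6e-06). The Na,K-ATPase subunit Atp1b2 (-1.63 ± 0.21), the metallothioneins Mt1 (-1.56 ± 0.14) and Mt2A (-1.48 ± 0.10) and transferrin, Tf (-1.32 ± 0.19), were also higher in the stria vascularis. So were Igf1 (-1.24 ± 0.10), the adhesion molecule Vcam1 (-1.17 ± 0.15), the complement genes C3 (-1.22 ± 0.15) and C4b (-1.51 ± 0.40) and Il1b (-1.50 ± 0.26). Higher in the organ of Corti were the neurofilaments Nefm (5.48 ± 0.32, at least 19.5-fold, adjusted p = 1.9e-07), Nefl (4.09 ± 0.21) and Nefh (3.71 ± 0.17). Further genes higher there were Oprk1 (5.92 ± 0.40), Sncg (4.06 ± 0.29), Pcp4 (3.50 ± 0.43), Fez1 (3.24 ± 0.35), Mapk8ip2 (3.21 ± 0.38), Mbp (3.08 ± 0.23) and somatostatin, Sst (2.74 ± 0.30). In the stria vascularis Oprk1 and Pcp4, like Nefm, were not above background in any condition (at least 29.4-fold and 4.56-fold). In 1 or 2 conditions the same held for Nefl, Nefh, Sncg, Fez1, Mapk8ip2 and Mbp (at least 15.3-fold, 12-fold, 12-fold, 2.51-fold, 5.54-fold and 5.93-fold). For Sst, C3, C4b and Il1b both regions were affected and no bound is given. Of 15 neuron genes 10 were higher in the organ of Corti, and adjusted over the list alone 12 were (camera adjusted p = 4.8e-11, and 0.036 with an estimated correlation). Inflammatory and injury genes were lower in the organ of Corti in 9 of 26 cases and higher in 1, and adjusted over the list alone in 10 and 1 (adjusted p = 1.4e-06, and 0.012 with an estimated correlation). Of 8 antioxidant enzymes 5 were lower in the organ of Corti, also when adjusted over the list alone (adjusted p = 3e-05, and adjusted p = 0.085 with an estimated correlation). The calls of 27 synaptic genes (6 higher, also adjusted over the list alone, adjusted p = 0.032), 7 stria vascularis markers (3 lower and 1 higher, also adjusted over the list alone, adjusted p = 0.029) and 4 endothelial genes (2 lower, and adjusted over the list alone 2 lower and 1 higher, adjusted p = 0.037) were lost, at adjusted p = 0.12 with an estimated correlation for each. Each was also lost with quantile normalization (adjusted p = 0.052). By limma 217 probe sets passed, 142 higher and 75 lower in the organ of Corti, with an all-gene median of 0.13, and with each array centred on its median 100 were higher and 157 lower. In native samples alone the list adjusted p was 2e-14 for neurons, 0.08 for inflammatory genes and 0.00017 for antioxidant enzymes. Normoxic cultures alone gave 116 and native samples alone 90, where 6 of the 20 genes named by size lost their call. Sst was at 0.23 in native tissue and 4.22 in normoxic culture, C4b at -0.56 and -2.83, and C3 at -0.42 and -1.40.

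Between modiolus and stria vascularis, Gap43 was 27-fold higher in the modiolus (4.75 ± 0.17, adjusted p = 3.1e-09) and Mbp at least 17.8-fold (4.66 ± 0.25), followed by Nefm (4.58 ± 0.34), the adhesion molecule Ntm (3.92 ± 0.50), Sst (3.53 ± 0.32), Nefl (3.48 ± 0.22), Foxd1 (3.30 ± 0.48), Il6 (3.18 ± 0.55), the synaptotagmin Syt4 (2.68 ± 0.33) and Pcp4 (2.39 ± 0.46). The stria vascularis had more Kcne1 (-3.97 ± 0.35, 15.6-fold), S100a1 (-2.78 ± 0.12), Cpz (-2.49 ± 0.26), Mt3 (-2.43 ± 0.31), Mt1 (-2.35 ± 0.15), the growth factor binding protein Igfbp2 (-2.34 ± 0.13), Atp1b2 (-2.29 ± 0.22), Tf (-2.23 ± 0.21), Fgfr4 (-2.20 ± 0.18) and Nnat (-2.15 ± 0.29). In the stria vascularis Nefm, Ntm, Foxd1 and Pcp4 were not above background in any condition (at least 10.4-fold, 4.37-fold, 4.71-fold and 2.11-fold), and Nefl and Syt4 were not in part of the conditions (at least 10-fold and 5.76-fold). In the modiolus Cpz and Mt3 were not in 1 condition (at least 5.31-fold and 5.23-fold), and for Sst and Il6 both regions were affected and no bound is given. Of 7 stria vascularis markers 4 were lower in the modiolus, also adjusted over the list alone (camera adjusted p = 0.00046, and adjusted p = 0.13 with an estimated correlation), namely Kcne1, Atp1b2, Atp1b1 (-2.03 ± 0.20) and Kcnq1 (-1.49 ± 0.37, in part not above background in both regions). The Atp1b1 difference was not seen in native tissue, at a signal of 72700 in the modiolus and 68100 in the stria vascularis. Normoxic cultures had 6000 and 4780 in the modiolus, and 49100 and 36900 in the stria vascularis. Of 15 neuron genes 9 were higher, and adjusted over the list alone 10 were higher and 1 lower (adjusted p = 0.0044, and adjusted p = 0.26 with an estimated correlation). Of 7 Schwann cell and myelin genes 5 were higher, and adjusted over the list alone 6 were higher and 1 lower (adjusted p = 0.04, and adjusted p = 0.24 with an estimated correlation), and with each array centred on its median 2 were higher and 1 lower (adjusted p = 0.067). Antioxidant enzymes were lower in the modiolus in 3 of 8 cases, and in 4 adjusted over the list alone (adjusted p = 0.00013, and adjusted p = 0.14 with an estimated correlation). HIF targets and glycolysis genes were lower in 2 of 7, and in 4 adjusted over the list alone (adjusted p = 0.04, and adjusted p = 0.24 with an estimated correlation), with Slc2a1 at -1.19 ± 0.22, and the call was lost with quantile normalization (adjusted p = 0.19). By limma 321 probe sets passed, 211 higher and 110 lower in the modiolus, where the median of all genes was 0.35. With quantile normalization 123 were higher and 126 lower, with each array centred on its median 79 and 176, and the named genes kept their direction under both. In native samples and normoxic cultures alone the list adjusted p was 1.3e-07 and 0.42 for neurons, 0.047 and 0.0036 for stria vascularis markers, 0.088 and 0.076 for Schwann cells and myelin, 0.00039 and 0.0036 for antioxidant enzymes, and 0.39 and 0.4 for HIF targets. Normoxic cultures alone gave 150 and native samples alone 116, where 9 of the 20 genes named by size lost their call. Syt4 was at 0.55 in native tissue and 3.96 in normoxic culture, Sst at 1.23 and 4.78, Mt3 at -0.56 and -3.62, and Mt1 at -1.11 and -2.71. Of the probe sets called in the region comparisons, 91.1% to 95.9% had the same sign in session 1 alone, 96.9% to 100% in session 2 and 96.9% to 100% in session 3. The arrays of each session were part of the calls, so that these shares are no independent check.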

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

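The tests of degraded RNA and of neuronal RNA in the modiolus cultures were chosen only after the results were seen. Culture changed 42 probe sets by different amounts in the 3 regions, in a direct test of the difference. The adjusted p was 0.00011 for Nefh, 0.00092 each for Serpine2, Nes and Sncg, and 0.0015 for Enpp2. With 1 probe set per gene 22 genes passed, and the culture difference was lowest in the modiolus for 13 of them, in the stria vascularis for 8 and in the organ of Corti for 1.

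A scan session effect stays open, since all native arrays came from session 1 and a session effect that differs between regions cannot be told apart from this pattern. That the native modiolus pool held another tissue stays open. Of 93 probe sets higher in cultured modiolus than in both other regions, 65 (69.9%) were also higher in the native modiolus array than in each other native array. Interchangeable native arrays would give 25%, but 2 of them were repeats of the organ of Corti, so that this is no exact chance level. With 1 array a partial mixture and a true pool cannot be told apart. Less neuronal RNA in modiolus cultures stays open too. The median of the 15 neuron genes lay lower in the modiolus than in the organ of Corti by -0.74, but 5 of these genes had themselves passed the test between regions. For the other 10 the median was -0.30, at percentile 12.08 among 10000 random lists of like level, with 6 lower and 4 higher. Of all 15, 10 were lower in the modiolus and 5 higher, which were Gap43, Map1b, Cntn1, Ntrk3 and Syn1. Nerve fibres cut from their cell bodies, a difference in cell survival and a change of expression within neurons were not tested.

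The GAPDH 5′ control probe set, which no comparison uses, had a mean signal of 22562 ± 4944 (SD, n = 4) on native and 126036 ± 17923 (SD, n = 12) on cultured arrays, 5.59-fold higher in culture. Its 3′ probe set was 1.74-fold and the 3′ probe set of actin 1.16-fold higher.

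The rise of inflammatory and stress transcripts in culture was weighed against the technical differences between the same arrays. All 15 members of the inflammatory list that rose also rose under quantile normalization and with arrays centred on their medians. For these genes this argues against the choice among these scalings. Centring could change little, since the median log2 signal was 9.32 to 9.65 on native and 9.32 to 9.69 on normoxic arrays. All of these scalings assume a like total signal on every array, which was not tested. Degraded RNA in the native pools stays open: 2 of 3 control transcripts had a 3′ to 5′ ratio above every cultured array in every native array, hexokinase at 4.49 to 14 against 1.56 to 3.34 besides GAPDH, while actin did not (1.67 to 2.41 against 1.73 to 2.78). Scan session and culture cannot be told apart by design. The difference between sessions 2 and 3 was 0.16 of the size of the culture difference (medians 0.20 and 1.22 over the 404 probe sets called). These probe sets were picked for their culture difference, which favours a low ratio, and the ratio does not measure session 1. Among the 15 risen list members the largest difference between sessions 2 and 3 was 1.15. The smallest culture difference among them was 0.99, which may belong to another gene. A response of the tissue to dissection and culture stays open beside degraded RNA and scan session.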

How the results depend on the processing

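Models of single scan sessions and with session 3 as a term were chosen only after the results were seen. Of 178 results for named genes, 42 lost their call in at least 1 alternative, 8 gained one and 5 changed sign, and 4004 values kept direction and side of the threshold. The averaged hypoxia count of 2 became 1 with pseudocount 1 and with quantile normalization, 4 with centred arrays, with the filter on dim probe sets and with the replicate block, 6 with scan session as a term, 0 without the variance trend, with arrayWeights and in session 2 or session 3 alone, and 0 to 3 leaving out 1 array (0 except without either normoxic stria vascularis array or hypoxic stria vascularis replicate 1). In the modiolus the count of 1 became 0 with pseudocount 1, centred arrays, no variance trend, arrayWeights and the replicate block, and 0 to 2 leaving out 1 array (0 except without normoxic modiolus replicate 1, hypoxic modiolus replicate 2 or either normoxic stria vascularis array). In the stria vascularis the count of 3 became 0 with centred arrays and with only the arrays compared, 1 without the trend, 5 with the replicate block, 6 with the session term, and 0 to 5 leaving out 1 array (0 except without either normoxic organ of Corti array, normoxic modiolus replicate 1 or hypoxic stria vascularis replicate 1). The hypoxia test between regions gave 0 to 1. Leaving out 1 array, the culture count was 353 to 415, in the organ of Corti 121 (without native replicate 1) to 221, in the modiolus 215 to 271, in the stria vascularis 109 (without normoxic replicate 1) to 183 (85 with only the arrays compared, fewer samples), and between regions 26 (without normoxic organ of Corti replicate 2) to 48 (14 without the trend, 81 with the replicate block, 68 with a random session block, 88 with session 3 as a term). The organ of Corti against the modiolus gave 238 to 300 (69 in native samples alone), against the stria vascularis 188 to 220 (116 in normoxic cultures and 90 in native samples alone), and the modiolus against the stria vascularis 256 to 315 (150 and 116), the single conditions resting on fewer samples. The native modiolus and stria vascularis arrays could not be left out. Gene lists called for hypoxia were 0 with an estimated correlation, 0 with fry and 1 in session 2 alone (2 in the main model); for culture 2 and 15 (8); for the organ of Corti against the modiolus 0 and 6 (2); against the stria vascularis 2 with an estimated correlation (6); and for the modiolus against the stria vascularis 0 and 12 (5). Small hypoxia values changed sign: Hif1a was 0.06 in session 3 alone; Bax 0.09 in session 2 alone and -0.12 to 0.04 without 1 array; Jun -0.04 with quantile normalization, -0.05 with centred arrays, -0.10 in session 2 alone and -0.09 to 0.11 without 1 array; Hspa1a -0.01 with centred arrays, -0.15 in session 2 alone and -0.14 to 0.24 without 1 array. For culture, Fos was -0.03 to 0.18 without 1 array, the lowest without native organ of Corti replicate 1. Where no smaller sample is named, the cause was not tested. Signals near the foreign-sequence controls (95th percentile 237 to 772) limit dim genes such as Calcrl.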

Other observations

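The test of the stria vascularis alone, the splits within sessions and the fits within single sessions were chosen only after the results were seen. Ion channel and receptor genes that fell in normoxic culture were not set apart from other genes as lists. Of 39 potassium channel genes 6 fell and 5 did adjusted over the list alone, among them Kcnj11 (-1.98 ± 0.26) and Kcnj1 (-1.12 ± 0.23). Of 10 sodium channel genes 3 fell, also adjusted over the list alone, which were Scn1a (-2.07 ± 0.63), Scn9a (-1.72 ± 0.45) and Scn7a (-1.37 ± 0.21). Of 12 calcium channel genes 4 fell, also adjusted over the list alone, with Cacna2d1 at -1.20 ± 0.21. Of 21 genes of GABA and glycine signalling 4 fell, also adjusted over the list alone, among them the synthesizing enzyme Gad1 (-1.56 ± 0.39) and the receptor Gabbr1 (-1.36 ± 0.22). The camera adjusted p was 0.4, 0.49, 0.26 and 0.56 for these lists. By fry, which makes no comparison with other genes, the 3 channel lists lay lower on balance (adjusted p = 0.02, 0.02 and 0.014), and GABA and glycine signalling did not pass (adjusted p = 0.051). Among 7 genes of astroglia and supporting cells 2 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.95, median -0.35 but mean 0.11), with glutamine synthetase, Glul, at 1.74 ± 0.14 and the glutamate transporter Slc1a3 at -1.31 ± 0.15, another probe set of Slc1a3 passing in the opposite direction. Of 23 neurotrophic genes 3 rose and 4 fell, also adjusted over the list alone (adjusted p = 0.34), with the neurotrophin receptor Ntrk2 at -1.40 ± 0.43. Icam1, of the endothelial list, rose by 2.04 ± 0.11. Against groups not above background, the falls of Kcnj11 and Cacna2d1 were at least 3.31-fold and 2.23-fold, and Scn1a, Scn9a, Gad1 and Ntrk2 have no bound.

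Several neuropeptide genes, singled out after their values were seen, were among those whose culture difference varied between the regions. Cck was at 3.35 in the organ of Corti, -0.47 in the modiolus and 3.28 in the stria vascularis (adjusted p of the difference = 0.011). Npy was at 0.44, 2.87 and -0.72 (adjusted p = 0.011), somatostatin at 4.03, 3.59 and 0.04 (adjusted p = 0.021), and Penk at 1.34, 2.95 and 0.75 (adjusted p = 0.034). Cck and somatostatin were not above background in native tissue where they rose, by at least 5.5-fold and 3.39-fold for Cck in the organ of Corti and stria vascularis and 5.51-fold and 10.8-fold for somatostatin, Sst, in the organ of Corti and modiolus. The pump subunit Atp1b1 was at -0.61, -3.76 and -0.68 (adjusted p = 0.0063). Between regions, the neurotrophin Ntf3 was higher in the organ of Corti than in the modiolus (1.34 ± 0.22, adjusted p = 0.00067) and the stria vascularis (2.36 ± 0.22, adjusted p = 8.6e-06), and Chrna9, the cholinergic receptor of hair cells, was higher in the organ of Corti than in the stria vascularis (2.02 ± 0.47, at least 2.57-fold, adjusted p = 0.0085). The potassium channel Kcnk1 was higher in the organ of Corti than in the modiolus (2.17 ± 0.14, adjusted p = 2.8e-07). Hair cells were represented by 3 measured list genes and macrophages by 1, too few for a list test.

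The lower level of inflammatory and injury genes after hypoxia was weighed as a hypothesis. That 1 scan session carries it is argued against, since the gap between the list median and the median of all genes was -0.18 in session 2 and -0.17 in session 3. Of 100 splits of the 12 cultured arrays, only the real one gave a gap of means as large (0.33, highest other 0.29), a narrow margin. The list was 1 of 21 tested for hypoxia in the same arrays and had the smallest p, which this count does not allow for. Chance is therefore not excluded. The list lost its call with an estimated correlation (camera adjusted p = 0.076) and did not pass by fry (adjusted p = 0.054). Whether the stria vascularis alone carries it stays open, since without its arrays the gap was -0.10, with -0.07 in the organ of Corti, -0.20 in the modiolus and -0.26 in the stria vascularis, and the members went both ways. A candidate explanation, which was not tested, is a damped inflammatory response of explants that passed through hypoxia, which may differ between the regions.

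A further hypothesis was that hypoxia moved genes against the culture difference. Across 720 genes, which are not independent replicates, the hypoxia and culture differences correlated at r = -0.303, but both use the normoxic arrays, and data simulated with no effect gave -0.437. The covariance was -0.118 against -0.056 simulated. With the normoxic arrays divided by session the correlation was -0.201 and -0.08 and the covariance -0.103 and -0.044. The median hypoxia difference in sessions 2 and 3 was -0.196 and -0.064 for 65 genes over 2-fold higher in culture and 0.183 and 0.055 for 88 over 2-fold lower, but these genes were picked with the same normoxic arrays. The simulated data held no culture difference, which affects the size of a correlation, so that those correlations are not comparable. The covariance was larger in size than simulated. The values from divided normoxic arrays share none of these arrays and were negative, so that they do not arise from sharing. They have no estimate of spread, and whether a true relation exists stays open.

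Other splits of the same arrays were fitted to see whether chance can be excluded. It can for culture, where 1 of 54 splits, the real one, gave as many probe sets (404, highest other 102). These splits cannot separate culture from scan session, since all native arrays came from session 1. Chance can also be excluded for the organ of Corti against the modiolus (1 of 100, with 302 and 213), against the stria vascularis (1 of 100, with 217 and 109), and for the modiolus against the stria vascularis (1 of 36, with 321 and 93). For hypoxia it cannot in the model without session, where 7 of 100 splits gave at least the real count of 2. The highest other count, 45, came from the split that follows scan session, which points to a structure of the samples by session. With session as a term and labels exchanged within region and session, 1 of 32 splits, the real one, gave as many (6, highest other 0). This test was added after the results were seen, when the planned one had not excluded chance, so that it does not settle the question.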
